A study of Homo sapiens with 6 samples.

How the data were processed

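H441 is an established human lung adenocarcinoma cell line. Per the labels, its cells received either a scrambled control siRNA or siRNA against ETS2 by lipid transfection, and total RNA was taken 48 h later. Each group holds 3 arrays, each from its own transfection according to the labels. Biotin-labelled cRNA was hybridised to an Affymetrix human gene array, on which 1 probe set stands for a transcript and is called a probe here.

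The deposited values are log2 expression levels, 1 column per array, rounded to 2 decimals. RMA, which corrects background, normalises between arrays and summarises the probes of a transcript, is named in the submitters' processing notes. Its settings and version, the annotation and the genome build are not given in the sources used here. No coordinates are printed for that reason. The log2 scale was checked on the values, which ran from 3.21 to 14.51 with array medians between 8.07 and 8.10. RMA brings arrays to a common distribution, so a shift shared by all genes would be removed, and it compresses the folds of dim genes. The number of arrays limits the precision.

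The value table held 33297 probes. The platform annotation listed 21214 of them, 19460 with 1 gene symbol and 1754 with several; the other 12083 were unnamed here. Of the probes with 1 symbol, 19429 were matched by gene identifier to a current gene record of the RefSeq annotation of GRCh38.p14, used for names alone, and 0 symbols changed. Where a gene had more than 1 probe, the probe with the highest mean over all 6 arrays was used, which left 18417 genes. Of these, 769 had more than 1 probe. Among the 41 of them that changed, 4 had probes pointing in both directions. Probes with several symbols or none were tested separately. A background floor was set at the 95th percentile of the mean values of 346 olfactory receptor genes, a log2 value of 6.72. No gene was left out for being dim, and 12888 genes (70.0%) lay above the floor in at least 1 group.

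Differences are ETS2 siRNA minus control siRNA on the log2 scale. They were fitted over all 6 arrays with limma 3.58.1 in R 4.3.3, using lmFit and eBayes without an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all genes. A gene counts as changed at an adjusted p under 0.05. Errors of levels are SDs over 3 arrays, and errors of differences are limma's moderated standard errors with 95% intervals. An exact permutation of 3 arrays against 3 cannot give a p under 0.1, so single genes were tested only in the model across genes. The arrays come from separate transfections of 1 cell line, and the p-values measure the spread between those transfections.

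Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list's members with all other genes, adjusted over 30 lists. The lists held 901 distinct genes, of which 819 were measured. They covered ETS factors, HGF-MET signalling, other receptor tyrosine kinases, ERK output, cell cycle, p53 and apoptosis, inflammation and interferon, cell identity, matrix and adhesion, metabolism, stress responses, the RNA interference machinery and markers of leukocytes, fibroblasts and endothelium. The same lists were run through camera with an estimated correlation and through fry. The directional p of fry asks whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction. Neither compares the list with other genes. Each list's mean was also set against 10000 random lists of the same size matched on mean level.

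The genes named are ETS2 and MET; the 15 largest rises and 15 largest falls among changed genes whose groups did not overlap and with at least 1 group mean above the floor, leaving out small RNA and uncharacterised symbols; and, per list, up to 4 changed members with the largest change, or the 2 with the smallest p where none changed. Other genes are said to be chosen after their values were seen. The design, the lists, this rule and the alternatives were fixed before the data were examined. The alternatives were the replicate number as a block, 3 rescalings of the arrays, 2 filters on dim genes, the mean over a gene's probes, all probes tested on their own, 2 other variance models, array weights, each array left out in turn and 3 other list tests.

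The procedure was tested on simulated data for this comparison, made over all 18417 genes with the spread of the arrays. It called 24 of 67 genes changed by a log2 value of 0.25 (35.8%), 52 of 67 changed by 0.5 (77.6%) and 65 of 66 changed by 1 (98.5%), with 8 false calls among 149 (5.37%). A list shifted by 0.1 was called, and 0 of the others were. The simulation held 149 calls against 904 in the data, so a call needed a smaller unadjusted p in it. The shares called therefore need not hold for the data. The simulated genes were drawn independently, so false list calls from correlation between genes were not covered.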

Results

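ETS2 encodes a transcription factor of the ETS family that acts downstream of RAS and ERK signalling. The arrays compared H441 lung cancer cells 48 h after transfection of siRNA against ETS2 with cells given a scrambled control siRNA, 3 arrays from separate transfections in each group. The comparison asks which transcripts change when ETS2 is lowered in these cells. MET, which encodes the receptor for hepatocyte growth factor, was included among the genes to report. Values are RMA levels on the log2 scale, and differences are given as ETS2 siRNA minus control.

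ETS2 itself fell by 1.05 on the log2 scale, to 48.4% of its control level. Its level was 9.83 ± 0.07 (SD, n = 3) in control cells, with arrays at 9.79, 9.91 and 9.79, and 8.78 ± 0.09 (SD, n = 3) after ETS2 siRNA, with arrays at 8.87, 8.70 and 8.78. The standard error of the difference was 0.0565, the 95% interval ran from -1.18 to -0.92, and the adjusted p was 0.000254. ETS2 was read by 1 probe, number 8068593. MET stood at 13.30 ± 0.03 in control cells and 13.28 ± 0.03 after ETS2 siRNA (SD, n = 3). Its difference of -0.02 had a 95% interval from -0.11 to 0.07 and an adjusted p of 0.863, and was smaller than the spread between replicates.

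In all, 904 of 18417 genes changed (4.91%), ETS2 included, 420 higher and 484 lower after ETS2 siRNA. At an unadjusted p under 0.05 there were 3409 genes. The balance of directions turned with the scaling of the arrays, to 475 higher and 442 lower when median-centred, 590 and 504 when quantile-normalised again and 557 and 253 when scaled on ribosomal protein genes, and with 1 array left out the count lay between 213 and 735. Most changes were small, with a median absolute log2 change of 0.26 among the changed genes, a fold of 1.20. A change of at least 1.5-fold was reached by 27 genes, 12 higher and 15 lower, and one of at least 2-fold by 2 genes, ETS2 and RAB3B. The groups did not overlap for all 904 changed genes and for 4249 genes in total (23.1%), where chance gives 10%. At least 1 group mean lay above the background floor for 883 of the 904.

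RAB3B, a small GTPase of regulated secretion, rose most, from 9.08 ± 0.09 to 10.23 ± 0.13 (SD, n = 3), a log2 difference of 1.14 (SE 0.0751, adjusted p = 0.000492). CHST4, a sulfotransferase that modifies glycans, rose from a control level of 6.71, just below the floor of 6.72 and so at background, to 7.71. Its measured difference of 1.00 (SE 0.0606, adjusted p = 0.000342) therefore starts from a level that is not above background. TNS4, a focal adhesion protein of the tensin family, rose by 0.88 (SE 0.0421, adjusted p = 0.000254). HMOX1, the heme-degrading enzyme heme oxygenase 1, rose by 0.75, and SERPINB5, which encodes maspin, by 0.69. SPDEF, an ETS factor of secretory epithelia, rose by 0.68, from 8.28 ± 0.02 to 8.96 ± 0.01 (SD, n = 3). SH3D19 (0.63), the semaphorin SEMA7A (0.61), the actin regulator CAP2 (0.61), the coagulation factor subunit F13A1 (0.60) and the sialyltransferase ST3GAL1 (0.59) followed. GPAT3, an acyltransferase of glycerolipid synthesis, the anthrax toxin receptor ANTXR2 and ARHGAP18 rose by 0.57, 0.57 and 0.55. EYS rose by 0.66 on the brightest of its 5 probes, which ranged from -0.02 to 0.66, and was not called on the mean over them (0.15, adjusted p = 0.113).

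After ETS2, the largest fall among the genes tested was that of PGM2L1, an enzyme that makes glucose 1,6-bisphosphate, at -0.80 (SE 0.0430, adjusted p = 0.000254). A probe with several symbols (TMPRSS2, LOC285847 and FKBP5), tested apart from these genes, read -0.88. ACY1, which deacylates N-acetylated amino acids, and HSPA13, a member of the HSP70 family, each stood at -0.71. THAP12 fell by 0.68 and RDX, which encodes radixin and links the membrane to actin, by 0.67. APRT, the adenine salvage enzyme, fell by 0.64, RASSF3 by 0.62, the helicase HELZ by 0.61, APPBP2 by 0.61 and the RNA-binding protein RBMS1 by 0.60. The 2 probes of RBMS1 read -0.60 and -0.31. The intraflagellar transport gene IFT52, NAALADL2 and the nucleoside transporter SLC28A3 each stood at -0.59, and CYP2B7P, a cytochrome P450 pseudogene transcribed in lung epithelium, at -0.58. All 30 of these largest changes stayed called with any single array left out.

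**Figure D1:**
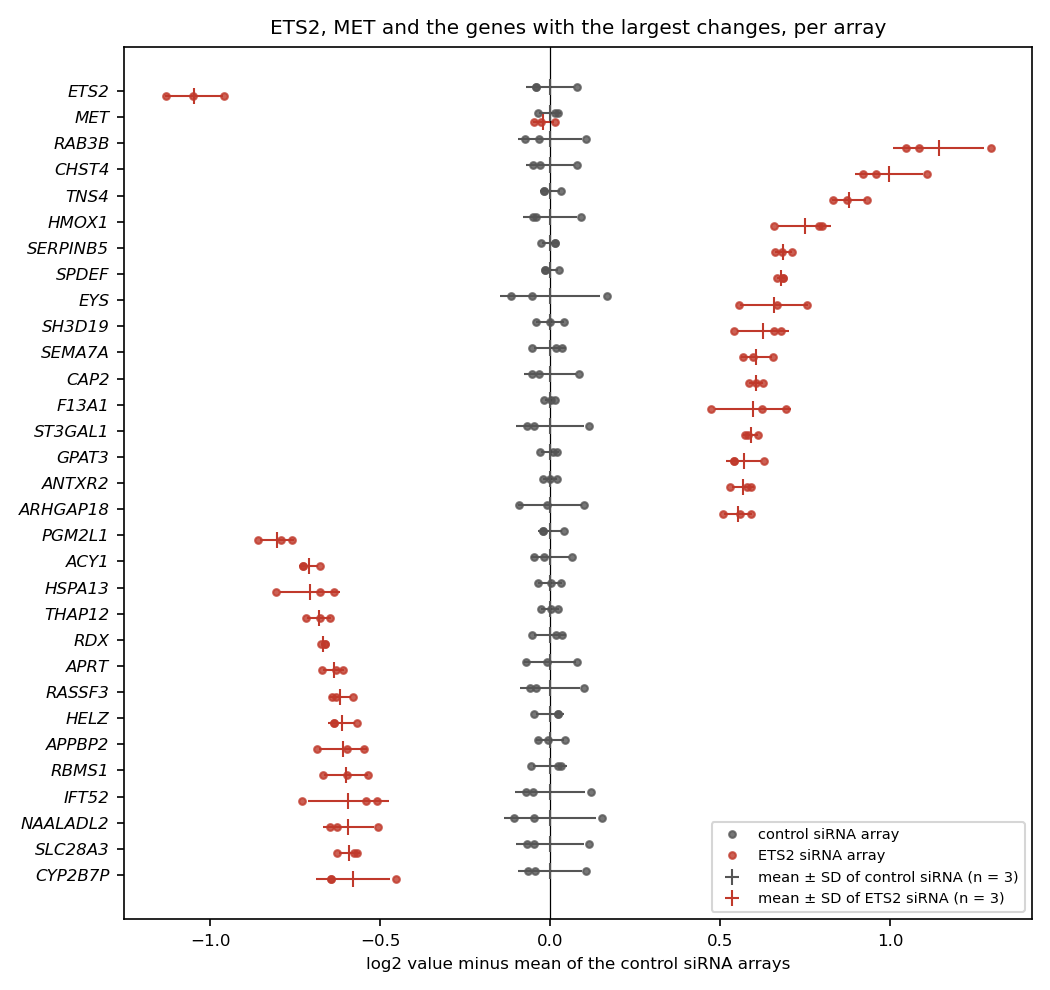
Log2 level of each array minus the mean of the 3 control arrays (horizontal axis), for ETS2, MET, the 15 largest rises and the largest falls (vertical axis); grey points are control siRNA arrays, red points ETS2 siRNA arrays, and ticks with bars are means ± SD (n = 3). ETS2 lies at -1.05 and RAB3B at 1.14 with no overlap between the groups, and the MET points of both groups overlap at a difference of -0.02.

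Of the gene lists, 8 of 30 were called by camera, 4 higher and 4 lower. The lists called higher were DNA replication and the G1/S transition (4 of 41 members rose and 1 fell), mesenchymal genes (6 of 28 rose), ERK output genes (6 of 27 rose) and YAP/TEAD and SRF targets (3 of 29 rose and 1 fell). The lists called lower were mitosis and G2/M (4 of 43 fell), replication-dependent histones (0 of 36 called), alveolar type II and club cell genes (5 of 26 fell and 1 rose) and inflammatory cytokines and NF-kB targets (4 of 34 fell). With an estimated correlation, camera called 0 of the 30 lists, with 1 list at an unadjusted p under 0.05. The directional test of fry also called 0, with 9 at an unadjusted p under 0.05, and its test for change in either direction called 28.

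In the DNA replication list, 37 of 41 members had positive differences, with a mean of 0.0893 and a median of 0.0867 (adjusted p = 9.25e-07 by camera; adjusted p = 0.746 with an estimated correlation). Over all genes, 4 members rose and 1 fell, and adjusted over the list alone 11 rose and 1 fell. CDC6, which loads the MCM helicase at origins, rose by 0.31 (SE 0.0673), the checkpoint mediator CLSPN by 0.26 and UHRF1, which helps copy DNA methylation, by 0.21. RRM1, the large subunit of ribonucleotide reductase, fell by 0.21. The mitosis list had a mean of -0.0461 and a median of -0.02 over 43 members (adjusted p = 0.0416; adjusted p = 0.863 with an estimated correlation), with 0 higher and 4 lower over all genes and 6 lower adjusted over the list alone. The kinesin KIF20A fell by 0.42 (SE 0.0364), HMMR by 0.36, the checkpoint kinase BUB1B by 0.28 and the mitotic kinase AURKA by 0.21. Of the 36 histone genes, 28 had negative differences, with a mean of -0.0495 (adjusted p = 0.0113; adjusted p = 0.746 with an estimated correlation). In that list 0 members were called over all genes or adjusted over the list alone, and H2BC11 (0.27, adjusted p = 0.0686) and H1-2 (-0.20, adjusted p = 0.0806) came closest.

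Genes of alveolar type II and club cells had a mean of -0.0924 and a median of -0.0850 over 26 members (adjusted p = 0.00648; adjusted p = 0.746 with an estimated correlation). Over all genes, 5 fell and 1 rose, and adjusted over the list alone 8 fell and 1 rose. Besides CYP2B7P, the water channel AQP4 fell by 0.55 (SE 0.0740), surfactant protein gene SFTPB by 0.36 and the phosphate transporter SLC34A2 by 0.29. The mesenchymal list had a mean of 0.0901 and a median of 0.0450 over 28 members, of which 11 lay below the floor (adjusted p = 0.0151; adjusted p = 0.746 with an estimated correlation). There 6 genes rose and 0 fell over all genes, and 6 rose and 1 fell adjusted over the list alone. The transcription factor SNAI2 rose by 0.46 (SE 0.0380), ZEB1, a repressor of epithelial genes, by 0.38, the fibronectin receptor subunit ITGA5 by 0.37 and the filament protein VIM by 0.37. The list of epithelial junctions and keratins was not called (mean -0.0283, adjusted p = 0.487), with RAB25 at -0.29, the epithelial transcription factor GRHL2 at -0.27 and MARVELD2 at 0.20 among its 3 called members of 27, and adjusted over the list alone 1 rose and 3 fell.

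ERK output genes had a mean of 0.0665 over 27 members (adjusted p = 0.0113; adjusted p = 0.746 with an estimated correlation), with 6 higher and 0 lower over all genes and 8 higher and 1 lower adjusted over the list alone. KLF6 rose by 0.27, the phosphatase genes DUSP4 and DUSP5, whose products act on ERK, by 0.26 and 0.25, and the receptor EPHA2 by 0.25. YAP/TEAD and SRF targets had a mean of 0.0597 over 29 members (adjusted p = 0.0340; adjusted p = 0.746 with an estimated correlation), with 3 higher and 1 lower over all genes and 9 higher and 2 lower adjusted over the list alone. PTPN14, itself a regulator of YAP, rose by 0.36, CRIM1 by 0.32 and NT5E by 0.29, while CCN1, a widely used YAP target, fell by 0.35. Inflammatory genes had a mean of -0.0607 over 34 members (adjusted p = 0.0416; adjusted p = 0.746 with an estimated correlation), with 0 higher and 4 lower both over all genes and adjusted over the list alone. The cytokine IL6 fell by 0.46 (SE 0.0556), PTGS2, the inducible cyclooxygenase, by 0.38, the chemokine CXCL2 by 0.29 and the adhesion molecule ICAM1 by 0.17.

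HGF-MET signalling was not called as a list (mean -0.0258 over 26 members, adjusted p = 0.487), with 1 higher and 2 lower both over all genes and adjusted over the list alone. Its changed members were MUC20 (-0.35), RAP1A (-0.26) and CRKL (0.19). Among ETS factors other than ETS2, 25 measured, SPDEF rose, while GABPA fell by 0.28 and the epithelial factor ELF3 by 0.23 (list adjusted p = 0.989; 1 higher and 3 lower adjusted over the list alone). The 2 probes of GABPA read -0.28 and -0.08. Of the receptor tyrosine kinases and EGFR ligands, HBEGF rose by 0.26 and EPHA2 as above (28 members, adjusted p = 0.989; 3 higher and 1 lower adjusted over the list alone), and the mean of 0.0062 had the opposite sign to the median of -0.02 and to camera's direction. Interferon-stimulated genes went both ways, 4 higher and 2 lower of 38 over all genes and 5 and 3 adjusted over the list alone, with SAMD9 at 0.27, IFIH1 at 0.26, IFITM1 at -0.31 and CXCL10 at -0.80. Both group means of CXCL10 lay below the floor. The mean of that list was -0.0107 and its median -0.0067, against an upward direction from camera (adjusted p = 0.989).

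Death receptor genes TNFRSF10A and TNFRSF10B rose by 0.43 and 0.31 within the apoptosis list, where BMF fell by 0.25 (27 members, adjusted p = 0.271; 3 higher and 2 lower adjusted over the list alone). TNFRSF10B and the polymerase POLH (0.22) were the 2 changed p53 targets of 25 (adjusted p = 0.0755; 2 higher adjusted over the list alone). Of 24 NRF2 targets, HMOX1, the glutathione synthesis gene GCLM (0.29) and SRXN1 (0.19) rose (adjusted p = 0.0755; 5 higher adjusted over the list alone). In the glycolysis and hypoxia list of 29, PFKFB3 fell by 0.28 and VEGFA by 0.23 (adjusted p = 0.188; 2 lower adjusted over the list alone). The serine synthesis gene PSAT1 (-0.29) and SHMT2 (-0.22) fell in the list of ATF4 targets and the unfolded protein response, 33 genes (adjusted p = 0.867; 2 lower adjusted over the list alone). Cholesterol synthesis had FADS2 at 0.18 and TM7SF2 at -0.22 among 26 genes (adjusted p = 0.188; 1 higher and 1 lower adjusted over the list alone). SERPINB5 and the collagenase MMP13 (-0.30) changed among 27 matrix proteases and inhibitors (adjusted p = 0.867; 3 higher and 2 lower adjusted over the list alone).

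Single members changed in 5 further lists that were not called. These were THBS1 (-0.21) of 22 TGF-beta targets (adjusted p = 0.138; 2 lower adjusted over the list alone), ERAP1 (0.23) of 11 HLA and antigen presentation genes (adjusted p = 0.542) and WDR43 (-0.26) of 29 ribosome biogenesis genes (adjusted p = 0.666). The others were LAMP2 (-0.18) of 30 lysosome genes (adjusted p = 0.666) and TNRC6C (0.23) of 13 genes of the RNA interference machinery (adjusted p = 0.670; 2 higher and 1 lower adjusted over the list alone). Adjusted over the list alone, ERAP1, WDR43 and LAMP2 were again the 1 call of their lists. The HLA list had a mean of 0.0364 and a median of -0.0033. Besides the histones, 5 lists had 0 members called by limma, over all genes or adjusted over the list alone. They were oxidative phosphorylation (35 genes, adjusted p = 0.632; COX6C -0.17, NDUFV1 -0.11), leukocyte markers (21, 0.666; CD68 0.17, ITGAM -0.16), squamous genes (25, 0.670; KLK7 -0.17, KLK10 0.20), fibroblast and endothelial markers (21, 0.867; FAP 0.19, KDR -0.18) and cytosolic ribosomal proteins (39, 0.900; RPL22 -0.10, RPS7 0.11). The ribosomal list had a mean of -0.0015 and a median of 0.0033. KLK7 and FAP had means over all arrays below the floor.

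**Figure D2:**
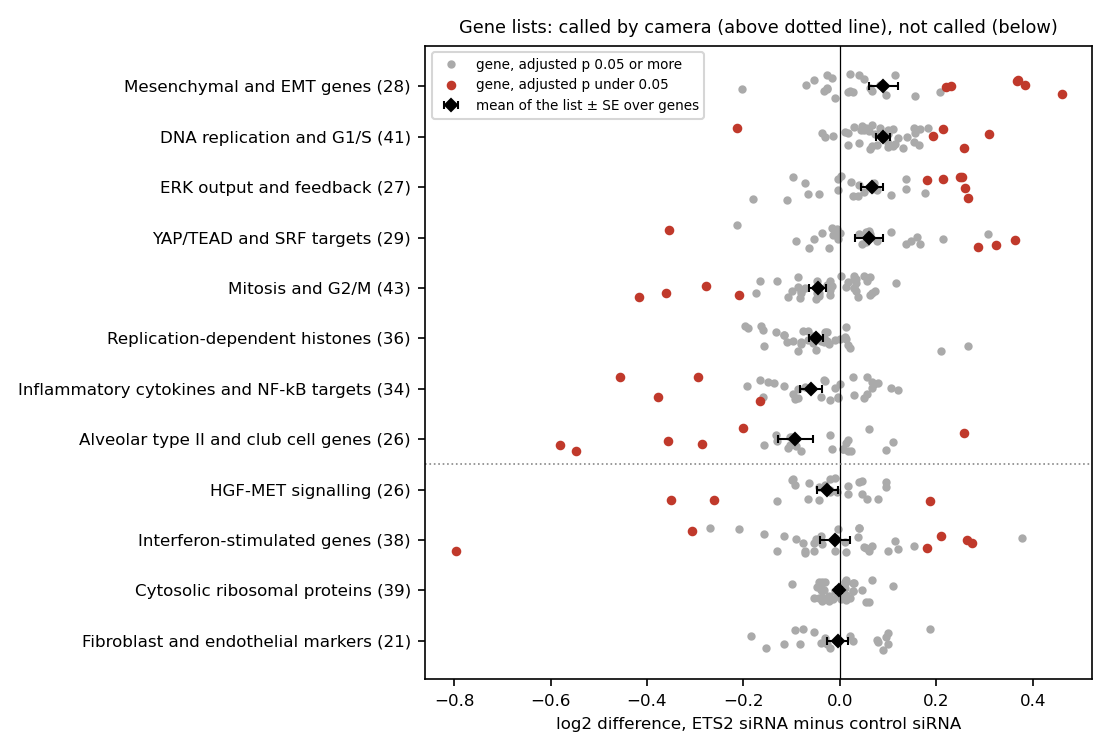
Log2 difference, ETS2 siRNA minus control siRNA (horizontal axis), of each measured member of 12 gene lists (vertical axis, with the number measured); red points have an adjusted p under 0.05, grey points do not, and diamonds are list means ± SE over genes. The 8 lists above the dotted line were called by camera, with means from -0.0924 for alveolar and club cell genes to 0.0901 for mesenchymal genes, and the 4 below it were not.

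The replication and alveolar lists were called with any single array left out. Leaving out 1 array ended the other list calls. Without ETS2 siRNA replicate 1, the ERK list rose to an adjusted p of 0.0535 and the histone list to 0.269. The mesenchymal list was lost without that array or control replicate 2 (up to 0.165), and YAP/TEAD targets without it, control replicate 1 or control replicate 3 (up to 0.0751). Inflammatory genes were lost without replicates 1 or 2 of either group (up to 0.174), and the mitosis list without ETS2 siRNA replicate 1 or control replicates 1 or 2 (up to 0.540). The mitosis list was also lost when arrays were median-centred or scaled on ribosomal protein genes, with a mean of -0.0095 under the latter against -0.0461. Of the 58 changed list members named outside the largest changes, between 13 (without ETS2 siRNA replicate 3) and 42 (without control replicate 2) were still called with an array left out, and 10 of the 58 stayed called with any single array left out.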

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

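The tests of 1 deciding array, of array scaling, of dividing cells, of an interferon response and of fibroblast or endothelial RNA were chosen after the results were seen; the count of splits was not. The test for dividing cells was changed after earlier results were seen.

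Outside the gene-level test, 13837 probes carry several symbols (1754) or none here (12083). Of these, 68 (0.491%) changed when all probes were tested, 21 of them higher after ETS2 siRNA than in control cells and 47 lower, which is why they are given here. Some of these probes hold identical values on all arrays, so that the 68 are 56 distinct readings, 21 higher and 35 lower. Several symbols were carried by 32 (8 distinct readings higher and 12 lower) and 36 were unnamed, and the log2 changes ran from -0.88 to 0.95. Their genes were not analysed here.

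With the real grouping 904 genes changed, and the highest count among the other splits of the 6 arrays was 0. Of the 10 splits, 1 gave as many genes, the real one, and 10 splits are too few for a share under 0.05. Transfected RNA can induce interferon genes, but the median of the interferon-stimulated genes was -0.0067 (camera adjusted p = 0.989), far below the larger changes. Both groups received siRNA, so a response shared by them would cancel, and the median speaks only to a difference between the siRNAs. Unintended targets of the siRNA and a loss of ETS2 both remain open, since 1 siRNA reagent was compared with 1 control.

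The replication list was called higher, with 4 of 41 members higher and 1 lower, and the mitosis list lower, with 4 of 43 lower (adjusted p = 0.746 and 0.863 with an estimated correlation). Fewer dividing cells would lower replication, mitosis and histone genes alike, and 2 of these 3 lists were called lower, mitosis and histones. The replication list went the other way, with 37 of 41 members positive and a mean of 0.0893 (SE 0.0137 over genes). For that list this argues against fewer dividing cells as worded here, while the mitosis and histone calls go with it. These calls were known when the count was chosen, so the count restates the pattern and decides nothing. Earlier versions compared the replication and mitosis means (difference 0.136, SE 0.0158 over arrays, and 0.135, SE 0.0219 over genes). They also restated the pattern and decide nothing. Without ETS2 siRNA replicate 1 the histone call was lost (camera adjusted p = 0.269). Scaling that depends on level is not in line with a replication mean at percentile 100 of random lists matched on level, and the lowest replication mean with 1 array left out was 0.0759 (SE 0.0135). For the mitosis list, whose mean without ETS2 siRNA replicate 1 was -0.0295 (adjusted p = 0.540), a real shift and the weight of 1 array cannot be told apart. That list was called in 7 of 19 alternative settings and was lost under median-centring and under ribosomal scaling, where its mean was -0.0095 against -0.0461, so for it the scaling of the arrays stays open too.

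In the alveolar and club cell list 5 of 26 members fell and 1 rose, and in the mesenchymal list 6 of 28 rose and 0 fell (adjusted p = 0.746 for each list with an estimated correlation). RNA of fibroblasts or endothelium would raise their markers. All arrays are of H441, an established cell line, so the design holds no such cells. Readings of these markers come from cultures of that line. The upper end of the 95% interval over genes of the markers' mean was 0.0387, against a median of 0.37 for the called mesenchymal genes. That median holds only genes that were called higher, so it overstates a shared shift. The comparison alone therefore decides nothing, and it is the use of a cell line that leaves such RNA without a source in the design. Of those 21 markers 8 lay above the floor, 4 listed genes are also on the mesenchymal list, and the abundant fibroblast transcripts COL1A1 (8.95 to 9.05), COL3A1 (7.04 to 7.06) and LUM (9.03 to 8.98) did not pass the test. The alveolar mean lay at percentile 0 of random lists matched on level, against an effect of level-dependent scaling. No biological explanation was tested, and the mesenchymal call was lost without control replicate 2 or ETS2 siRNA replicate 1 (adjusted p up to 0.165). The list's mean ran from 0.0730 to 0.1025 with 1 array left out.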

How the results depend on the processing

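None of the settings given here were chosen after the results were seen. ETS2 was called under each of 17 alternatives, from -1.09 to -1.005, and MET under none, from -0.04 to 0.02 (adjusted p from 0.679 to 0.968). The count of genes changed at least 1.5-fold stayed within 1.5 times 27. Of the 904 changed genes, 0 turned sign where tested, which covered 891 and 881 of them under the 2 filters on dim genes. Their groups did not overlap, so leaving out or weighting arrays could not turn a sign, and this count does not measure stability there. Against 420 higher and 484 lower, testing all probes gave 399 (170 and 229) probes. Leaving out genes below the floor and fitting anew gave 1434 (706 and 728) genes, and an intensity trend 1963 (989 and 974). Array weights gave 1480, 780 of them higher, and 4 lists. For the floor filter, the trend and the weights the cause was not tested. Scaling on ribosomal protein genes gave 557 higher and 253 lower, 68.8% higher against 46.5%, with the median of all genes moved to 0.04; the balance also turned under median-centring (475 and 442), repeated quantile normalisation (590 and 504), the trend, array weights and without control replicate 2 (412 and 323). With 1 array left out and fewer samples, 213 to 735 genes changed, 96 to 412 higher and 117 to 323 lower, with 2 to 10 lists. The lowest count was without ETS2 siRNA replicate 3; the counts were 421 without control replicate 1, 356 without control replicate 3, 377 without ETS2 siRNA replicate 1 and 274 without ETS2 siRNA replicate 2. Of the lists, an estimated correlation and fry called 0 and camera on ranks 4; the cause was not tested. For named genes, 1413 gene and setting pairs kept their status, called or not called, 265 lost the call and 17 gained it. For lists these counts were 520, 46 and 4. Pairs called in neither fit count as kept whatever their sign, and 8 of the 30 lists were called in the main fit. The 1413 and 520 are therefore not counts of stable calls. Whether the replicate numbers pair the arrays stayed open, and the main fit took them as unpaired. The deviations of same-numbered arrays correlated at 0.177, 0.181 and 0.0352 across genes, and those of other pairs at -0.198 to 0.0659. The third pair did not correlate best with its own number. With the number as a replicate block 604 genes changed, 279 higher and 325 lower, 563 of them shared with the 904, and 5 lists were called; the cause was not tested. The block ended the mitosis, inflammatory and YAP/TEAD calls. The mitosis list was also lost under median-centring, ribosomal scaling, both filters and array weights, the YAP/TEAD list under the 25th percentile filter, and the histone, mesenchymal and inflammatory lists under array weights. Ranks ended the mitosis, inflammatory, mesenchymal and YAP/TEAD calls. Signal over background limits the dim genes, and 70.0% of genes had a group mean above the floor.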

Other observations

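The tests of 2 cilium lists were written before their result was seen. The symbol families that prompted them, the test without genes carrying an IFT or BBS synonym, and the genes named in the first paragraph were chosen after their values were seen.

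Several further genes outside the lists changed. CD274, which encodes PD-L1, rose by 0.49 and the hyaluronan receptor CD44 by 0.45, as did CDK6, a G1 kinase, by 0.45. The shared cytokine receptor subunit IL6ST fell by 0.52 and the interleukin 1 co-receptor IL1RAP by 0.46. GRHL3, an epithelial transcription factor, fell by 0.50. Next to SERPINB5, its relative SERPINB7 rose by 0.53.

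Genes sharing a symbol stem were tested as 311 families of at least 8 members, and 0 passed camera after adjustment, with 30 at an unadjusted p under 0.05 and 2 with an estimated correlation. Low values were reached by RFX at an adjusted p of 0.209 (8 genes, mean -0.145; 3 fell, RFX7 by 0.40, RFX5 by 0.35 and RFX3 by 0.29), the SNORD small nucleolar RNAs at 0.209 (115 genes, mean -0.0516; 3 fell), the mucins at 0.209 (15 genes, MUC20 -0.35 and MUC4 -0.28), the intraflagellar transport genes at 0.243 (18 genes, mean -0.104; IFT52 -0.59 and IFT46 -0.38) and, among those at the same adjusted p, the CXCL chemokines (14 genes, mean -0.131; 4 fell). RFX3 and, among the CXCL genes that fell, CXCL10 (-0.80) lay below the floor in both groups. The GALNT glycosyltransferases lay higher at 0.243 (17 genes, GALNT5 0.30 and GALNT3 0.27).

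Since some RFX factors drive ciliary genes, a lower ciliary programme was a hypothesis. The 45 primary cilium genes outside these symbol stems had a mean of -0.0153, with a 95% interval over genes from -0.0526 to 0.0220 and a camera p of 0.537. Of them 0 rose and 1 fell, ARL6, but 10, ARL6 included, carry an IFT or BBS symbol as a synonym, and a missed threshold does not exclude a fall. Without those 10, 35 genes had a mean of 0.0059 with an interval from -0.0290 to 0.0408. Its lower end lay above the mean of the IFT genes, -0.104, and above their median, -0.045. The IFT mean is pulled down by IFT52 and IFT46, and the family was picked for its low values. The interval also takes genes as independent, so this is only a weak argument against a general fall of that size. A smaller fall stays open. The 35 motile cilium genes had a mean of 0.0073 and a camera p of 0.742, and with 21 of them below the floor this list decides nothing.

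Control replicate 2 stood apart from the other arrays on the second principal component, at -9.21, which held 24.0% of the variance; the first component (41.2%) separated the groups. Differences between control arrays had an SD of 0.0994 to 0.134, and those between ETS2 siRNA arrays one of 0.0928 to 0.106.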
